A study of Mus musculus with 6 samples.

How the data were processed

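Small RNA was sequenced from the brain cortex of adult male mice in 6 libraries, 3 labelled Fmr1 knockout (KO) and 3 labelled wild type (WT). Per the labels' protocols, total RNA was extracted from whole cortices, adaptors were ligated to both ends, and the products were amplified by PCR, size-selected on a gel and read from a single end. Bowtie, DESeq2 and the mouse genome build mm10 are named in the submitters' processing notes, without versions or settings. Adaptor trimming, the miRBase release, the mismatches allowed, the treatment of reads that match several places, the use of strand and the caller of predicted miRNAs are not given in the sources used here.

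The deposited table gives whole-number read counts for each mature miRNA, per the file headers and the values themselves, with no normalization. It has 1182 features in all. Of these, 1140 carry miRBase names and 42 are predicted miRNAs. Per the file headers the authors also deposited TPM values. Each TPM value equals the read count divided by the column total and scaled to a common sum per library, with no length term, and the largest deviation from this was 4.9e-10. The TPM columns therefore hold no information beyond the counts and were used for an alternative test alone. The column names carry an extra letter compared with the sample titles, and each was matched to the title with the same number. There were 0 columns of values that belonged to no sample.

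Genotype was taken from the label of each sample. Replicate numbers follow accession order within a genotype and only name a library. The labels say that the replicates are biological and that genotypes were siblings of matched age, but do not tie each library to a separate animal. The p-values therefore measure the spread between these libraries. No litter, day or batch is given. Chi-square statistics of the counts of library pairs within a genotype were at least 47.7 per degree of freedom, so no library looked like a duplicate of another.

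Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with too few reads were removed with filterByExpr at its default minimum count of 10, which left 541 miRNAs, 536 annotated and 5 predicted. Library sizes were scaled by TMM, with factors from 0.8265 to 1.092, and CPM values are on this scale. Fold changes are KO relative to WT from the edgeR quasi-likelihood test with robust estimation, with Benjamini-Hochberg adjustment over all 541 miRNAs and a threshold of 0.05. Standard errors of log2 fold changes were obtained from the same fit. Intervals are 95% intervals of the fold change and, like the p-values, rest on 3 libraries per genotype.

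Alongside single miRNAs, 19 lists of miRNAs were fixed from textbook knowledge before the data were examined. They were neuronal, activity-regulated, FMRP-linked, oligodendrocyte, microglia and leukocyte, reactive glia, erythroid, endothelial and mural, choroid plexus and multiciliated, and Hox-cluster miRNAs, the miR-200 family, the X-linked cluster beside Fmr1, other X-linked miRNAs, the imprinted Dlk1-Dio3 cluster, and the let-7, miR-29, miR-30, miR-17-92 and miR-181 families. Lists with at least 3 tested members were compared with all other tested miRNAs by camera in limma 3.58.1, on log2 CPM with a preset correlation of 0.01, and adjusted over 17 lists. List differences are means over members of the difference in log2 CPM. Fold changes of single members come from edgeR, which compares mean levels. Camera with an estimated correlation served as an alternative. The fry test asks instead whether a list differs from no change, so its p-values answer another question.

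The miRNAs named in the text were set by a rule fixed in advance. It takes any that passed the threshold with non-overlapping groups, the 10 with the smallest p where fewer passed, the 5 most abundant, and up to 4 members of each list by mean CPM. Within that limit, 4 members were named for lists that passed the threshold of the list test and 2 for the others, with miR-451a and miR-29c-5p added after their values were seen. Names outside the rule were chosen after their values were seen and are marked so.

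Hairpins were placed by name on GRCm38, the assembly of mm10, with the GENCODE M21 annotation. This gave positions for 1109 annotated names, 526 of them tested. Mature sequences were not used here, so the GC fraction of a miRNA was taken from its arm of the hairpin. Because the use of strand is not stated, miRNAs from opposite strands of a locus may share reads. Where their counts are near-identical they cannot be told apart. The table held 14 pairs of miRNAs whose counts agreed within 3% in every library with at least 200 reads in total. Members of families that differ by few bases can also share reads.

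Summed counts ranged from 11182888 to 15733876 per library, with both members of near-identical pairs included. Reads are not unique molecules, since no molecular identifiers are described. The procedure was tested on simulated counts for the 541 miRNAs with 200 of them changed, in 10 rounds. It recovered 14.9% of miRNAs changed by a factor of 1.5, 52.2% at a factor of 2 and 90% at a factor of 4, with 2.6% false calls. A list of 10 miRNAs lowered by 0.5 on the log2 scale passed the list test in 10 of 10 rounds and an unshifted list in 0. These results apply to the simulated settings. With 200 of 541 miRNAs changed, the adjusted threshold is easier to pass than where few change. Recovery in the real data may therefore be lower. In the real data, members of the lists that passed had estimated correlations from 0.13 to 0.539. The rounds do not show how the list test behaves when members vary together to that degree. Totals and shares of reads were compared by exact permutation tests, which cannot give a two-sided p below 0.1 with 3 libraries per genotype.

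Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, limma-trend on log2 TPM with a pseudocount of 1, edgeR without robust estimation, 4 other scalings, no count filter, a mean CPM minimum of 10, annotated miRNAs alone, an adjusted p threshold of 0.1, and leaving out each library. All 10 splits of the 6 libraries into 3 and 3 were also run. Alternatives added after seeing the data were library quality weights, counting near-identical pairs once, and the miR-200 level as a covariate. Fmr1 mRNA is not measured by small RNA libraries, so the genotype labels were not checked against the deleted gene.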

Results

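Small RNA was profiled in the cortex of adult male mice lacking Fmr1 and of WT siblings, with 3 libraries per genotype. Fmr1 encodes FMRP, an RNA-binding protein that regulates translation in neurons and whose loss in humans underlies fragile X syndrome. MicroRNAs (miRNAs) are short RNAs that guide repression of messenger RNAs, and the comparison asks which of them differ in level in cortex without Fmr1. The KO libraries held 13422729, 14385332 and 11182888 miRNA reads and the WT libraries 14825686, 13225790 and 15733876. Between 875 and 914 miRNAs were detected per library. Totals did not differ beyond the spread between libraries (12996983 ± 1643124 in KO and 14595117 ± 1269841 in WT, SD, n = 3 each, exact two-sided permutation p = 0.3, adjusted p = 0.7 over 6 measures of depth and composition). The smallest p that this test can give is 0.1.

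The miRNA population was that of brain tissue in both genotypes. The most abundant miRNA was miR-9-5p, a neural miRNA, at 242800 ± 67500 CPM in KO and 216300 ± 9450 CPM in WT (SD, n = 3 each). Its hairpins lie on chromosome 13 (83738814 to 83738885), chromosome 3 (88215598 to 88215686) and chromosome 7 (79505264 to 79505353), all within long noncoding RNA genes. The next in abundance, miR-9b-3p, is annotated on the opposite strand of the chromosome 3 copy, and its counts stayed within 0.356% of those of miR-9-5p in every library. These reads therefore cannot be assigned to a strand. Neuron-enriched miR-128-3p followed at 97500 ± 7740 CPM in KO and 104400 ± 6540 CPM in WT. It derives from introns of R3hdm1 on chromosome 1 and of Arpp21 on chromosome 9. The mural-cell miRNA miR-143-3p reached 34540 ± 3650 CPM in KO and 30810 ± 3560 CPM in WT. For miR-26a-5p, whose hairpins lie in Ctdspl and Ctdsp2, the levels were 24100 ± 4880 and 31940 ± 864 CPM. None of these 5 passed the edgeR test, with log2 fold changes from -0.41 for miR-26a-5p to 0.17 for miR-9-5p and adjusted p-values of at least 0.72. Together they took 62.74% ± 4.99 of summed counts in KO and 60.29% ± 0.949 in WT (SD, n = 3 each, exact permutation p = 0.4). This share includes the near-identical counts of both miR-9-5p and miR-9b-3p and is therefore inflated if these are the same reads. Alone, miR-9-5p took 23.66% ± 3.23 in KO and 21.76% ± 0.314 in WT.

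No single miRNA differed between KO and WT cortex at an adjusted p below 0.05 (0 of 541, edgeR quasi-likelihood test). The miRNAs nearest to the threshold were miR-190a-5p, miR-30f, miR-136-5p, miR-376b-5p and miR-448-3p, with higher values in KO, and miR-300-3p, miR-181a-5p, miR-181b-5p, miR-191-5p and miR-433-3p, with lower values. In these 10 the KO and WT libraries did not overlap, yet each had an adjusted p of 0.694. At an unadjusted p under 0.05 there were 35 miRNAs, 18 higher and 17 lower, where 27 are expected by chance. With a library left out, this count ranged from 14 of 564 without WT replicate 2 to 97 of 560 without KO replicate 3. DESeq2, run on all 1182 features, gave 0 calls and 40 at an unadjusted p under 0.05, and limma-voom gave 0 and 33 of 541. Groups were non-overlapping for 85 miRNAs (15.7%, where chance gives 10% if both genotypes spread alike). The median SD of log2 CPM was 0.396 in KO and 0.14 in WT. Such unequal spread can raise the share that arises without a difference in level, so no excess over chance can be read from it. The median 95% interval reached 0.64 log2 units to either side of the estimate.

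**Figure D1:**
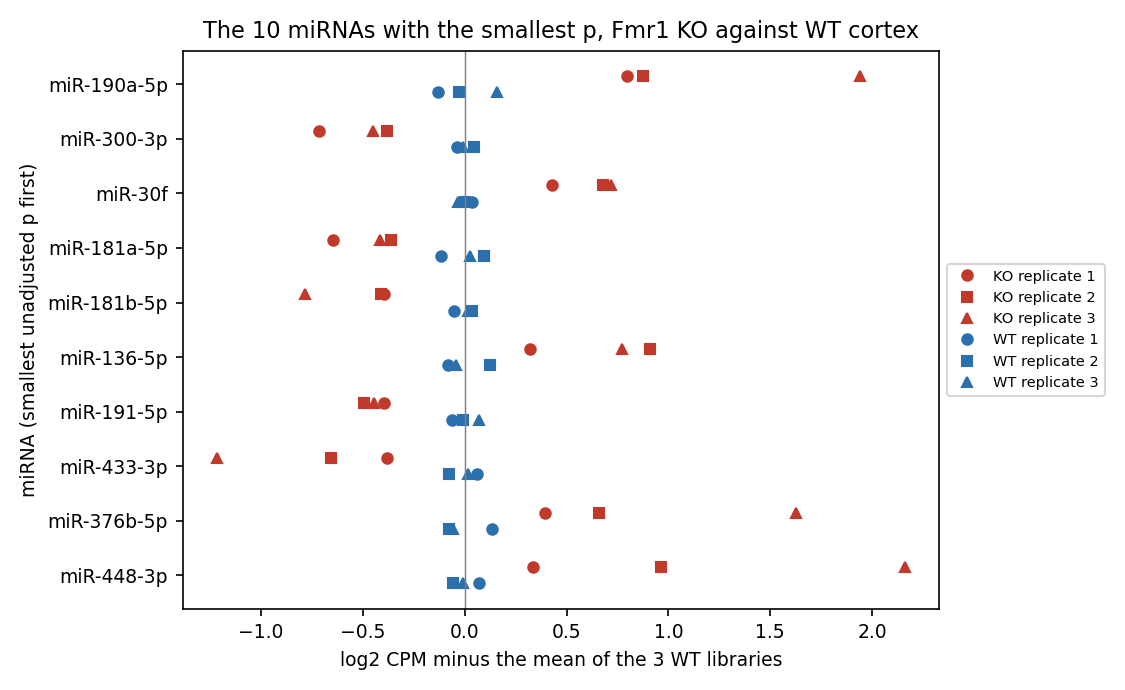
Level of the 10 miRNAs with the smallest p in each library, as log2 CPM minus the mean of the 3 WT libraries; red symbols are KO libraries, blue symbols WT libraries, and the shape gives the replicate. KO and WT libraries do not overlap for any of the 10, and KO replicate 3 lies farthest from WT for miR-190a-5p, miR-30f, miR-181b-5p, miR-433-3p, miR-376b-5p and miR-448-3p.

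Among the 5 with higher values, miR-190a-5p had 4.08 ± 1.96 CPM in KO and 1.66 ± 0.17 CPM in WT (SD, n = 3 each). This is a log2 fold change of 1.29 (SE 0.38, 95% interval 0.43 to 2.15). Its hairpin lies in an intron of Tln2, the gene of the cytoskeletal linker talin 2, on chromosome 9 (67236660 to 67236726, minus strand). The X-linked miR-448-3p, from an intron of the serotonin receptor gene Htr2c (X, 147158210 to 147158321, plus strand), had 11.4 ± 7.51 CPM in KO and 4.44 ± 0.194 CPM in WT. Its log2 fold change was 1.35 (SE 0.44), and its KO values were 5.6, 8.66 and 19.9 CPM. Levels of miR-30f were 96.8 ± 10.3 CPM in KO and 63.3 ± 1.47 CPM in WT, a log2 fold change of 0.61 (SE 0.18). It is annotated opposite the miR-30e hairpin in an intron of Nfyc on chromosome 4 (120772606 to 120772697). It may share reads with that hairpin, although it was in none of the near-identical pairs. In the lower direction, miR-191-5p had 743.6 ± 25.2 CPM in KO and 1013 ± 48.1 CPM in WT, a log2 fold change of -0.45 (SE 0.14). It is encoded on chromosome 9 (108568319 to 108568392), in an exon of a long noncoding RNA gene.

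Of the 10, 4 come from the imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are expressed from the maternal chromosome, many of them in neurons. These 4 went both ways. The cluster's list holds 74 of the 541 tested miRNAs and 7 of the 35 at an unadjusted p under 0.05 (edgeR). Whether 4 of 10 exceeds its share was not tested. Values of miR-300-3p (109724313 to 109724391, outside annotated host genes) were 1006 ± 120 CPM in KO and 1432 ± 44 CPM in WT, and those of miR-433-3p (109591715 to 109591838, opposite an exon of Rtl1) were 254.3 ± 70.8 and 416.5 ± 19.8 CPM. For miR-136-5p (109595327 to 109595388, also opposite Rtl1) they were 160.5 ± 32.6 CPM in KO and 99.8 ± 7.65 CPM in WT, and for miR-376b-5p (109723458 to 109723539) 169.4 ± 81.3 and 85.1 ± 6.96 CPM. Over the whole cluster, 28 of 74 tested members had higher and 46 lower values in KO, with 0 calls over all miRNAs or adjusted over the list alone. The mean difference of -0.11 log2 units did not pass the list test (camera, adjusted p = 0.131). Its most abundant members, miR-127-3p and miR-434-5p, had log2 fold changes of -0.20 (SE 0.21) and 0.01 (SE 0.23), the latter changing sign with the scaling.

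All 4 tested 5p members of the miR-181 family had lower values in KO, and the family passed the list test with a preset correlation (camera, mean difference -0.41 log2 units, adjusted p = 0.00969). The call was lost with an estimated correlation (adjusted p = 0.478). The family is abundant in brain and in lymphocytes. Levels of miR-181a-5p were 3505 ± 354 CPM in KO and 4867 ± 361 CPM in WT, a log2 fold change of -0.47 (SE 0.14). Those of miR-181b-5p were 974 ± 141 and 1397 ± 44.7 CPM, a log2 fold change of -0.52 (SE 0.16). The hairpins of both lie side by side on chromosome 1 (from 137966455) and on chromosome 2 (from 38852735, opposite an intron of Nr6a1). These 2 miRNAs passed at 0.05 when adjusted over the list alone (both 0.0217, edgeR), and 0 passed over all miRNAs. The other members, miR-181c-5p and miR-181d-5p from chromosome 8, had log2 fold changes of -0.43 (SE 0.27) and -0.17 (SE 0.16). The family's call was also lost without KO replicate 1 (mean difference -0.334, adjusted p = 0.124) and without WT replicate 2 (-0.339, adjusted p = 0.086). Against no change, rather than against other miRNAs, the adjusted p was 0.109 (fry).

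The let-7 family, regulators of developmental timing and differentiation that accumulate in mature neurons, passed the list test with a preset correlation (camera, mean difference -0.31 log2 units, adjusted p = 0.00838). With an estimated correlation the call was lost (adjusted p = 0.478). Values of all 9 tested 5p members were lower in KO, although let-7f-5p was slightly higher (log2 fold change 0.00246) when libraries were scaled without the 5 most abundant miRNAs, and without KO replicate 3 (0.0383). Levels of let-7i-5p, from chromosome 10 (122985640 to 122985724), were 14510 ± 2520 CPM in KO and 18590 ± 448 CPM in WT (log2 fold change -0.36, SE 0.16). For let-7g-5p, from an intron of Wdr82 on chromosome 9, they were 13130 ± 5900 and 17910 ± 533 CPM (log2 fold change -0.45, SE 0.32), and for let-7c-5p 4872 ± 584 and 5953 ± 227 CPM. The most abundant member, let-7f-5p, had 21200 ± 2880 CPM in KO and 22280 ± 847 CPM in WT. No member passed the edgeR threshold over all miRNAs or adjusted over the list alone. KO replicate 3 was the lowest library, at -0.55 relative to the WT mean, against -0.19 and -0.20 in the other KO libraries. Without it the mean difference was -0.18 (adjusted p = 0.0313). Against no change the adjusted p was 0.18 (fry).

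The third group past the threshold was that of choroid plexus and multiciliated cells, with higher values in KO for all 6 tested members (camera, preset correlation, adjusted p = 0.00969, mean difference 0.47). With an estimated correlation the adjusted p was 0.568. Its most abundant member, miR-204-5p, lies in an intron of Trpm3 on chromosome 19 (22750605 to 22750672) and had 1017 ± 526 CPM in KO and 697.9 ± 40.1 CPM in WT. The log2 fold changes were 0.54 (SE 0.32) for miR-204-5p, 0.49 (SE 0.27) for miR-204-3p, 0.26 (SE 0.25) for miR-34c-5p and 0.33 (SE 0.26) for miR-34b-3p. Members of the miR-34b/c hairpins are known from motile cilia. A single library carried most of this difference, since the list stood 1 log2 unit above the WT mean in KO replicate 3 and 0.0766 and 0.334 above it in KO replicates 1 and 2. Without KO replicate 3 the mean difference was 0.0994 (adjusted p = 0.603). The call was also lost, with mean differences of 0.369 and 0.446, without KO replicate 2 (adjusted p = 0.107) and without WT replicate 2 (adjusted p = 0.086), and over left-out libraries the mean difference ranged from 0.0994 to 0.677. With all libraries the adjusted p was 0.0675 without the count filter and 0.139 with near-identical pairs counted once. Against no change it was 0.492 (fry), and 0 members passed when adjusted over the list alone.

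**Figure D2:**
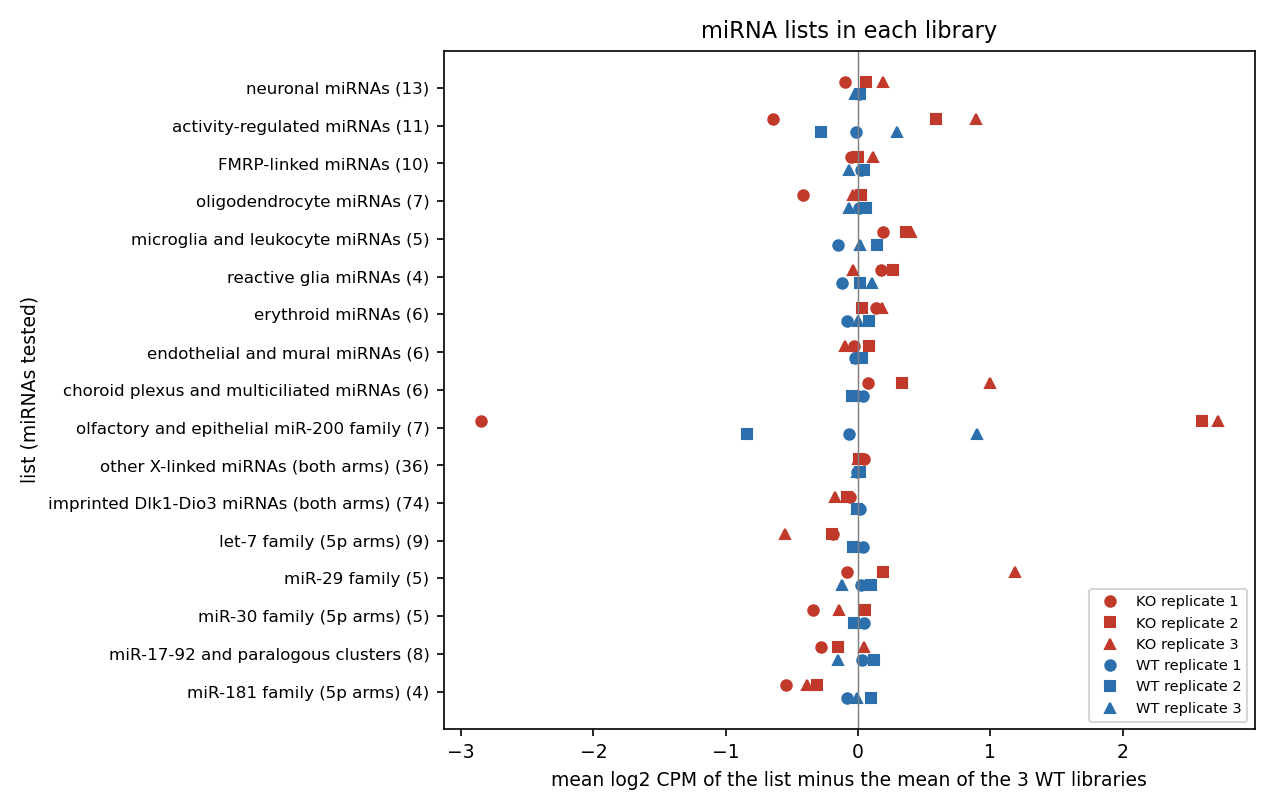
Mean log2 CPM of each tested list in each library, minus the mean of the 3 WT libraries; red symbols are KO libraries and blue symbols WT libraries, with the number of tested miRNAs in brackets. The miR-181 and let-7 families lie below the WT libraries in each KO library, the choroid plexus list is highest in KO replicate 3, and the miR-200 family ranges from -2.85 to 2.72 within the KO libraries.

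Neuronal miRNAs differed little between genotypes. Of 13 tested, 8 had higher and 5 lower values in KO, with a mean difference of 0.05 log2 units (camera, adjusted p = 0.637). The activity-regulated list, which holds miRNAs induced by neuronal firing, had 9 of 11 higher (mean difference 0.28, adjusted p = 0.54). In it, miR-132-5p had 2685 ± 107 CPM in KO and 2314 ± 28.4 CPM in WT, and miR-132-3p 1220 ± 360 and 1197 ± 9.3 CPM. The list also holds the miR-183 cluster, and its level relative to WT was -0.65, 0.59 and 0.90 in the KO libraries, in the order of the miR-200 family. For miRNAs linked to FMRP in earlier work, 6 of 10 were higher and 4 lower, with a mean difference of 0.02, a median of -0.0084 and a test direction of lower (camera, adjusted p = 0.973). The most abundant of them after miR-9-5p was miR-148a-3p, at 15730 ± 7480 CPM in KO and 10980 ± 1350 CPM in WT (log2 fold change 0.52, SE 0.35).

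Lists of other cell types did not pass the test. Oligodendrocyte miRNAs had 6 of 7 lower values (mean difference -0.14, camera adjusted p = 0.328), with miR-219a-2-3p at 655.5 ± 129 CPM in KO and 787 ± 60.9 CPM in WT. Its neighbour miR-219b-5p, annotated on the opposite strand of the same chromosome 2 locus, had 93.6 ± 12 and 111.9 ± 7.21 CPM. Microglia and leukocyte miRNAs were higher in 5 of 5 (mean difference 0.32, adjusted p = 0.131), among them miR-146a-5p at 101.3 ± 35.3 and 80.5 ± 1.93 CPM and miR-150-5p at 92.1 ± 25.1 and 80.4 ± 8.4 CPM. Reactive glia miRNAs split 2 and 2 (mean difference 0.14, adjusted p = 0.578). In that list miR-21a-5p had 8569 ± 745 CPM in KO and 8899 ± 423 CPM in WT, and miR-146b-5p 1608 ± 412 and 1727 ± 65.3 CPM. Erythroid miRNAs, a measure of blood in the tissue, were higher in 5 of 6 (mean difference 0.12, adjusted p = 0.54), with log2 fold changes of 0.03 (SE 0.19) for miR-486a-3p and 0.05 (SE 0.19) for miR-486a-5p. In the same list miR-451a had 53.2 ± 23.6 CPM in KO, with 80.1 CPM in KO replicate 3, and 33 ± 5.88 CPM in WT (log2 fold change 0.69, SE 0.31). Endothelial and mural miRNAs were higher in 5 of 6, with miR-126a-3p at 7749 ± 219 CPM in KO and 7229 ± 314 CPM in WT. For this list the mean was -0.0152, the median 0.11 and the test direction higher (adjusted p = 0.858). Of the Hox-cluster miRNAs, which mark hindbrain and spinal cord, 2 reached the count filter, too few for the list test. Levels of miR-10a-5p were 40.9 ± 18.7 CPM in KO and 35.7 ± 4.75 CPM in WT, and those of miR-10b-5p 40 ± 6.86 and 34.9 ± 3.74 CPM. The oligodendrocyte and erythroid counts each include both members of a near-identical pair, which are not separate evidence. In each of these lists 0 members passed over all miRNAs or adjusted over the list alone.

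The miR-200 family, characteristic of epithelium and of olfactory neurons, varied more within the KO group than between genotypes. Its summed level was 17.4, 973.6 and 1037 CPM in the KO libraries and 164.6, 89.9 and 310.8 CPM in the WT libraries. Mean levels were higher in KO for all 7 members, such as miR-200a-3p at 320.2 ± 277 CPM in KO and 82.9 ± 53.6 CPM in WT (log2 fold change 1.95, SE 1.53) and miR-200b-3p at 248.3 ± 207 and 77.7 ± 41.3 CPM, both from an intron of Ttll10 on chromosome 4. The mean difference in log2 CPM was 0.83 (camera, adjusted p = 0.328). KO replicate 1 lay below and KO replicates 2 and 3 above every WT library. Without KO replicate 1 the list passed with the preset correlation (mean difference 2.67, adjusted p = 4.76e-09), which treats its members as nearly independent. Their estimated correlation over all libraries was 0.989, and with it the adjusted p was 0.718. Without KO replicate 3 the mean difference was -0.11. The miR-183 cluster on chromosome 6 was likewise lowest in KO replicate 1 and highest in KO replicates 2 and 3, with summed levels of 45.9, 1147 and 1026 CPM in KO and 180.5, 85.3 and 433.9 CPM in WT.

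**Figure D3:**
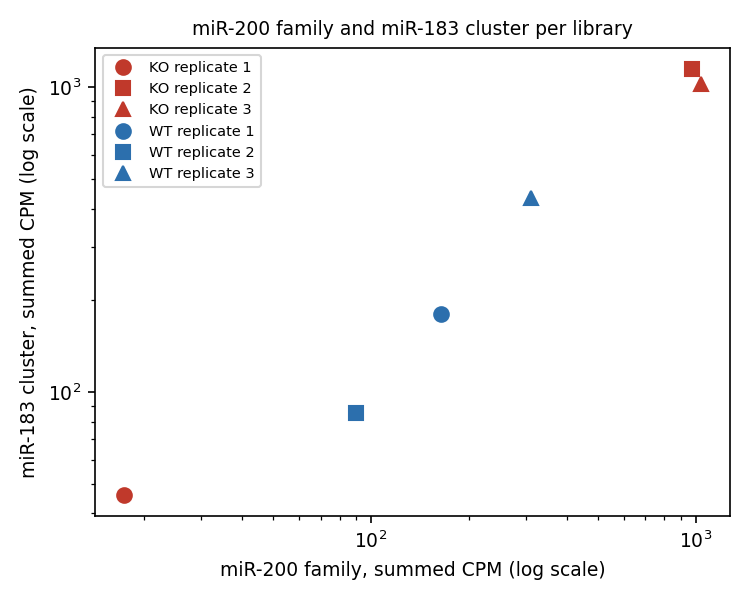
Summed CPM of the miR-200 family against that of the miR-183 cluster, both on log scales, with a symbol per library. Library values range from 17.4 to 1037 CPM for the miR-200 family, and the lowest and the highest library are both KO.

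Among X-linked miRNAs there was no common shift. Fmr1 is itself X-linked, and of the miRNA cluster that lies beside it a single member, miR-881-3p (66801944 to 66802021), reached the count filter, at 1.63 ± 0.768 CPM in KO and 1.88 ± 0.526 CPM in WT. Of 36 other X-linked miRNAs, 18 had higher and 18 lower values in KO (camera, direction higher, adjusted p = 0.858), while fry, which tests against no change, gave the direction as lower. The mean difference was 0.02 and the median -0.0751, with both members of a near-identical pair included. In this list miR-1298-5p, from an intron of Htr2c, had 2196 ± 1800 CPM in KO and 900.8 ± 118 CPM in WT, and miR-222-3p 868.5 ± 346 and 906.6 ± 103 CPM. The miR-29 family, which targets collagen and other matrix genes, had 4 of 5 higher values (mean difference 0.43, adjusted p = 0.0915), with miR-29a-3p at 1502 ± 416 and 1559 ± 112 CPM, miR-29b-3p at 139.9 ± 95.3 and 98.8 ± 5.12 CPM and miR-29c-5p at 74.5 ± 34.2 and 41 ± 2.42 CPM. This list lay 1.19 log2 units above the WT mean in KO replicate 3, without which the mean difference was 0.07, and it passed without KO replicate 1 with the preset correlation (adjusted p = 0.0178). The estimated correlation of its members over all libraries was 0.887, and with it the adjusted p was 0.694. In the miR-30 family 3 of 5 were lower (mean difference -0.14, adjusted p = 0.528), with miR-30d-5p at 18920 ± 4520 CPM in KO and 21420 ± 2410 CPM in WT and miR-30a-5p at 19340 ± 3740 and 18740 ± 416 CPM. For the miR-17-92 and paralogous clusters 6 of 8 were lower (mean difference -0.13, adjusted p = 0.41), while miR-25-3p had 140.5 ± 53 and 111.6 ± 2.54 CPM and miR-92a-3p 73.3 ± 22.8 and 84.8 ± 5.12 CPM. No member of these lists passed over all miRNAs or adjusted over the list alone.

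KO replicate 3 decided the count of single miRNAs. Without this library, edgeR called 18 miRNAs at an adjusted p below 0.05, 14 higher and 4 lower in KO, and 97 at an unadjusted p under 0.05. The smallest adjusted p, 0.00504, belonged to miR-148a-3p, at 19390 and 20680 CPM in KO replicates 1 and 2, 7120 CPM in KO replicate 3 and 9497 to 12130 CPM in WT. Its log2 fold change was 0.885 in this fit and ranged from 0.203 to 0.885 over left-out libraries. Also called higher were miR-146a-5p (log2 fold change 0.60, and 0.0398 to 0.601 over left-out libraries), miR-25-3p (0.63, 0.119 to 0.632) and miR-30f (0.57, 0.544 to 0.711). Called lower were miR-191-5p (-0.43, -0.485 to -0.401), miR-300-3p (-0.52, -0.614 to -0.402) and miR-433-3p (-0.50, -0.898 to -0.498). With a near-identical pair counted once, 17 were called. KO replicate 3 took no part in these calls. It lay on the same side of the WT mean as the other KO libraries in 8 of the 18, fewer than on the other side. The 8 include all 4 miRNAs called lower, although the same WT libraries entered both comparisons. Those on the other side were all called higher and include both members of the near-identical pair. Among them were miR-148a-3p, miR-146a-5p and miR-25-3p. Leaving out any other library gave 0 calls.

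The spread between libraries was wider in KO than in WT. The median SD of log2 CPM was 0.396 over the 3 KO libraries and 0.14 over the 3 WT libraries, and the SD was larger in KO for 452 of 541 miRNAs. It was 0.342 and 0.0823 for the 169 miRNAs with at least 1000 reads on average, miR-148a-3p, let-7g-5p and miR-1298-5p among them. The median absolute difference between libraries was 0.323 for KO replicates 1 and 2, 0.624 for KO replicates 1 and 3, and 0.488 for KO replicates 2 and 3, and at most 0.171 for pairs of WT libraries.

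**Figure D4:**
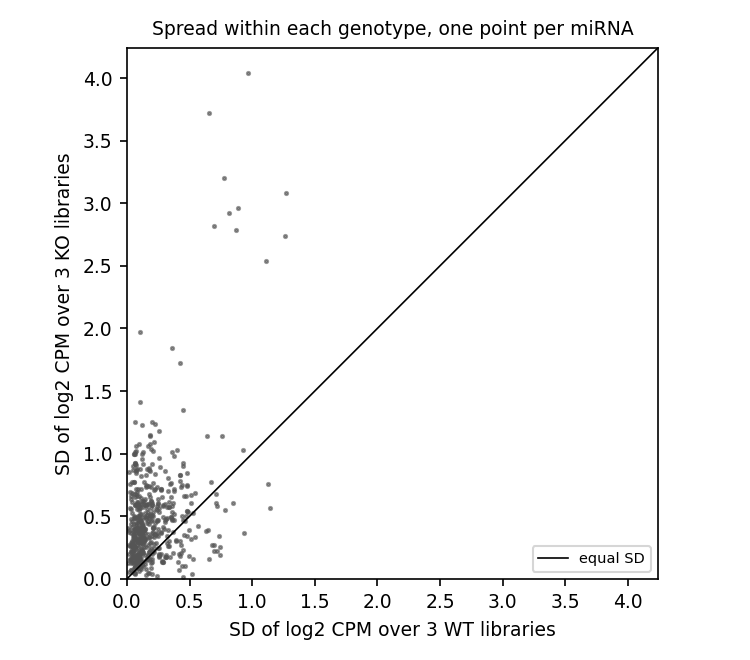
SD of log2 CPM over the 3 KO libraries against that over the 3 WT libraries, with a point per miRNA and a line of equal SD. Of 541 points, 452 lie above the line.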

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

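Library quality weights, counting near-identical pairs once and the miR-200 level as a covariate were chosen after seeing the data. The count of 0 miRNAs held under each setting that kept all 6 libraries, with 18 to 57 miRNAs of 303 to 1182 tested at an unadjusted p under 0.05 and smallest adjusted p-values from 0.218 to 0.962. Leaving out each library gave 0 to 18 calls, 18 without KO replicate 3, where fewer libraries entered the fit; the cause was not tested further. The count of 3 lists fell to 0 with an estimated correlation and ranged from 1 (without WT replicate 2) to 4 (without KO replicate 1) when a library was left out. The fry test, of lists against no change, gave 0. Differences in the share of the most abundant miRNAs kept their direction. Over 54 named miRNAs and all settings, 1074 values kept direction and side of the threshold, 7 passed the threshold, all without KO replicate 3, and 45 changed sign. Over 17 lists these numbers were 205, 2 and 16, the last counted by test direction. A further 13 did not pass where the main test did, 3 of them in fry, which is no loss of the same test. Scaling without the 5 most abundant miRNAs moved the median log2 fold change from 0.027 to 0.11. No paired analysis was possible because the labels give no shared replicate numbers. No value was given by the CPM minimum for the choroid plexus list, miR-190a-5p, miR-204-3p, miR-34b-3p, miR-448-3p and miR-881-3p, by counting pairs once for miR-9b-3p, or by the covariate for the miR-200 list, miR-200a-3p and miR-200b-3p. Depth left 541 of 1182 features with enough reads for the test.

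The cause of the sign changes was not tested; each concerns values that did not pass the threshold. With all libraries, they were miR-132-3p (-0.0127 in limma-voom, -0.0322 on TPM, -0.203 with quality weights, -0.0301 with the miR-200 covariate), miR-434-5p (-0.039 in limma-voom, -0.0598 on TPM, -0.027 with upper quartile, -0.0319 with totals alone), miR-486a-3p (-0.0113 on TPM, -0.00363 with upper quartile) and miR-30a-5p (-0.0125 with quality weights, -0.0451 with the covariate). Scaling without the top 5 gave 0.0249 for miR-21a-5p, 0.00246 for let-7f-5p and 0.0609 for miR-29a-3p, which was 0.00929 with the CPM minimum. Quality weights gave -0.0625 for miR-150-5p, 0.0124 for miR-21a-5p, 0.103 for miR-881-3p and -0.0497 for miR-29b-3p. For lists, changes were counted by test direction, and the values in brackets are mean differences. The FMRP-linked list, with a mean of 0.0223 but a direction of lower in the main test, turned to higher with totals alone (0.00405), RLE (0.0508) and no filter (0.122). Other X-linked miRNAs turned to lower in fry (0.0181, the mean of the main test) and with no filter (-0.014).

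Leaving out each library gave log2 fold changes from -0.104 to 0.346 for miR-9-5p and for miR-9b-3p, -0.224 to 0.142 for miR-132-3p, -0.00956 to 0.341 for miR-150-5p, -0.17 to 0.00556 for miR-21a-5p, -0.272 to 0.0962 for miR-146b-5p, -0.132 to 0.147 for miR-486a-3p, -0.105 to 0.163 for miR-486a-5p, -0.154 to 0.513 for miR-10a-5p, -0.608 to 0.122 for miR-881-3p and -0.383 to 0.203 for miR-222-3p. The ranges were -0.402 to 0.000556 for miR-127-3p, -0.264 to 0.253 for miR-434-5p, -0.161 to 0.0383 for let-7f-5p, -0.272 to 0.124 for miR-29a-3p, -0.199 to 0.808 for miR-29b-3p, -0.401 to 0.00934 for miR-30d-5p, -0.072 to 0.199 for miR-30a-5p and -0.377 to 0.0403 for miR-92a-3p. For lists, mean differences ranged from -0.00437 to 0.137 (neuronal), -0.0747 to 0.576 (activity-regulated), -0.00898 to 0.226 (FMRP-linked), -0.107 to 0.0412 (endothelial and mural), -0.107 to 2.67 (miR-200), -0.022 to 0.0564 (other X-linked) and 0.0688 to 0.701 (miR-29, whose test direction turned without KO replicate 3).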

Other observations

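The tests of a single deviating library and of the miR-200 family, with their bounds, were chosen after their results were seen, as were the miRNAs of the Htr2c introns, which are described but not tested as a group. Htr2c, an X-linked serotonin receptor gene with high expression in choroid plexus epithelium, hosts several miRNAs in its introns. All 6 that reached the count filter had higher mean levels in KO, and 4 of them were highest in KO replicate 3, none passing the edgeR threshold. Levels of miR-1298-5p (X, 147064905 to 147065002) were 898.2, 1443 and 4247 CPM in the KO libraries and 857.6, 810.2 and 1035 CPM in WT. For miR-1264-5p (X, 147010601 to 147010686) they were 18.8, 15.8 and 24.2 CPM in KO and 12.3, 11.6 and 13.5 CPM in WT. The other arms of these hairpins were not highest in KO replicate 3. Levels of miR-1298-3p were 76.58, 57.95 and 76.25 CPM in the KO libraries and 55.96 to 60.11 CPM in WT. Those of miR-1264-3p were 4.027, 5.636 and 3.709 CPM in KO and 3.755 to 4.26 CPM in WT. The choroid plexus miRNA miR-204-5p was likewise highest in KO replicate 3, at 1621 CPM against 663.9 to 765.8 CPM in the other KO libraries and 667.3 to 743.3 CPM in WT. Its other arm, miR-204-3p, had 12.45 CPM there and 10.59 CPM in WT replicate 3. Some miRNAs outside the choroid plexus list, named after their values were seen, were also highest in KO replicate 3. There miR-495-3p had 676 CPM (269.7 to 295.2 in WT) and miR-342-3p 263.4 CPM (83.27 to 99.18 in WT). The share of all miRNAs highest in that library was not counted.

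The KO libraries differed more from each other than the WT libraries did, with a median SD of log2 CPM of 0.396 in KO and 0.14 in WT, a ratio of 2.84. A single deviating library does not account for all of this, since KO replicates 1 and 2 differed by a median of 0.323 log2 units and the widest WT pair by 0.171, nor does counting noise, since the ratio was 4.15 among miRNAs with 1000 or more reads on average. Across miRNAs, the deviation from the WT mean correlated with GC content of the hairpin arm at 0.00666 in size in KO replicate 1. The correlation was -0.0906 in KO replicate 3, -0.261 in KO replicate 2 and -0.233 in WT replicate 2. This argues against a GC effect common to all KO libraries. It cannot exclude one in single libraries, and miRNAs are not independent replicates. Among the 10 splits of the libraries, 1 gave so large a ratio, the real one, the highest other being 1.94, and 10 splits are too few for a share under 0.05. Dissection, RNA quality and genotype itself were not tested and stay open.

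Levels of the miR-200 family and of the miR-183 cluster varied together over the 6 libraries, whatever the genotype. Their mean log2 levels had Pearson's r = 0.993 (exact permutation p = 0.00139) and Spearman's rho = 1 (exact permutation p = 0.00278), and r was 0.995 without the 2 libraries farthest from the median. The pair was chosen after its levels were seen, so these values describe the pattern and do not test tissue from another region or epithelium in the dissected cortex, which stays open. The family's range of 5.57 log2 units was 14 times the median range of the other 16 lists, so not all lists varied to the same degree. As the family was chosen after its levels were seen, this range describes the pattern and does not test a distortion of whole libraries. Genotype stays open, since 2 KO libraries lay above all WT libraries and the 1 below them excludes nothing by itself. All 7 family members also reached the count filter, in part through the libraries where the family was high. For example miR-141-3p, named after its values were seen, had 0, 4.878 and 3.38 CPM in the KO libraries and 0.2209 to 0.7893 CPM in WT. The 3 miRNAs of the miR-183 cluster are also in the activity-regulated list.

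Near-identical counts were found for 14 pairs of miRNAs, which held 22.41% to 27.73% of reads per library in their second members. Of 12 pairs with both hairpins placed, 11 (91.7%) lie on opposite strands of a locus, such as miR-9-5p with miR-9b-3p. This is consistent with reads being counted for both strands of a locus. Paralogous copies elsewhere account for few, since 1 of the placed pairs (8.33%), miR-467a-5p with miR-467b-5p, named after their counts were seen, lies at places that do not overlap. No biological explanation was tested, and counting each pair once left 0 called miRNAs and 37 at an unadjusted p under 0.05.

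Regrouping the libraries gave 10 splits, too few for a share under 0.05. The real split called 0 miRNAs, as did all 10, with a highest other count of 0. It gave 35 miRNAs at an unadjusted p under 0.05, reached by 1 of 10 splits, with a highest other count of 28. Its 3 lists were reached by 4 of 10 splits, with a highest other count of 4, in a split that set KO replicates 2 and 3 with WT replicate 1 against the rest.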
